A study of Mus musculus with 14 samples.

How the data were processed

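Messenger RNA was measured by RNA sequencing in 14 mouse libraries from 2 experiments. The first experiment used splenocytes of OT-1 mice, whose CD8+ T cells carry a receptor for an ovalbumin peptide. Per the labels' protocols, whole splenocytes received 1 µg/mL of the peptide and 200 U/mL interleukin-2 with 100 nM ND-646, an inhibitor of acetyl-CoA carboxylase, or with vehicle, for 3 days of activation and 4 days of expansion. The second experiment used CD8+ T cells sorted from spleen and from MCA205 fibrosarcomas 14 days after implantation under the skin of C57BL/6 mice. Libraries were poly(A)-selected and strand-specific and were read in pairs of 150 bases, per the labels' protocols.

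The authors deposited 2 tables of estimated counts per gene symbol, 1 per experiment, each with the same 55291 symbols. The submitters' processing notes name STAR, Salmon and DESeq2, without versions or roles. Aligner settings, genome build, annotation and the use of strand in counting are not given in the sources used here, so no coordinates are printed. The deposited estimated counts were taken as not normalized, because the column totals differ. Of all values, 9.16% in the first table and 9.15% in the second were not whole (tolerance 1e-06). Counts were rounded to whole numbers before testing. Estimated counts share reads between near-identical genes by a model, so paralogs such as the clustered granzymes and mitochondrial genes with nuclear copies are less certain than single-copy genes. Antisense and overlapping genes are uncertain for the same reason.

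Samples were grouped from their titles as vehicle (n = 4), ND-646 (n = 4), spleen (n = 3) and tumour (n = 3). All columns were matched to a sample. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical. Every pair of replicates differed by more than sampling noise in a chi-square test over genes, and none was counted as a duplicate. ND-646 libraries 1 and 4 were nearer each other (chi-square per degree of freedom 5.43), as were 2 and 3 (3.85), than libraries across these pairs (7.97 to 12.3). The labels name no batch, so whether the 4 ND-646 libraries are independent is not known. Totals ran from 23.5 to 33.8 M counts in the first experiment and from 19.6 to 21.0 M in the second. A count of 3 in a library, the most that a count of 0 allows, corresponded to 0.0887 to 0.153 CPM. Such floors cover counting error only.

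Each comparison was fitted within its own table in edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr, the robust quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are given with a standard error derived from the F statistic. CPM values are counts scaled to 1e+06 per TMM-scaled library, computed from the deposited counts. Folds against a group at 0 were bounded with 3 counts over that group. Gene lists, 24 in number with 569 genes, were fixed before the data were examined, as were the designs. Of these genes, 14 were not among the symbols of the tables. Lists of at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Composition measures were compared by two-sided exact permutation tests.

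Genes were named by a rule also set before the data were examined. It took Acaca, Acacb, Fasn and Cpt1a, and the 5 highest and 5 lowest log2 fold changes among called genes of at least 10 mean CPM whose groups did not overlap. Predicted genes and immunoglobulin or T cell receptor segments were left out of that part. It also took the 2 smallest p-values of each list on lipids, metabolism, T cell state, stress and growth, and the most abundant member of each list on cell types or RNA quality, or 2 where the list passed. For the overlap of the comparisons it took up to 3 genes per combination of directions. A gene that the rule took is not reported here. Other list members named in the text were chosen after their values were seen.

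On simulated counts, 50 genes were changed at each of 4 folds and 35 cell cycle genes were raised 1.5-fold. Of the former, the first comparison (14251 genes) recovered 48% at 1.25-fold, 78% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. The second (15042 genes) recovered 28%, 70%, 84% and 96% at those folds. False calls were 2.97% of 202 calls in the first and 2.79% of 179 in the second, calls of the 35 raised genes included. Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma-voom, other low-count filters, the replicate number as a block (7864 and 12492 calls), a 2-fold threshold and leaving out each library. Scaling by CD8 identity genes and restricting to genes detected in T cell libraries were added after the data were seen. Nuclear copies of mitochondrial genes were found with blastn 2.17.0+ among GENCODE M21 transcripts, at 95% identity over 200 bases or more. Figures were drawn with matplotlib.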

Results

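The data comprised 14 libraries of mouse CD8+ T cells or T cell cultures. In the first experiment, 4 libraries came from splenocytes cultured with ND-646 and 4 from those cultured with vehicle, for 7 days. In the second, CD8+ T cells came from 3 spleen and 3 tumour samples, and the labels call the tumour samples pooled without saying what was pooled, so what n = 3 stands for there is not known. Library totals (M, 1e+06 counts) averaged 25.2 ± 2.6 M in vehicle and 30.3 ± 2.84 M in ND-646 libraries (SD, n = 4 each; exact permutation p = 0.0857). Spleen and tumour libraries held 20.2 ± 0.509 and 20.3 ± 0.724 M (SD, n = 3 each; exact permutation p = 0.9, where 0.1 is the smallest possible).

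The first comparison asked how inhibition of acetyl-CoA carboxylase, which makes malonyl-CoA for fatty acid synthesis, altered the transcripts of activated splenocyte cultures. ND-646 cultures held far less mRNA of the clustered granzymes, the serine proteases of cytotoxic granules. Gzmc stood at 970 ± 62.4 CPM in vehicle and 46.9 ± 1.32 CPM in ND-646 libraries (SD, n = 4 each), 20.7-fold lower. All 36 cell cycle genes were also lower. Among the genes that rose was Vldlr, a lipoprotein receptor, at 1.75 ± 0.58 CPM in vehicle and 24.0 ± 2.82 CPM in ND-646 libraries. Of 14251 genes tested, 8028 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4247 higher and 3781 lower.

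**Figure D1:**
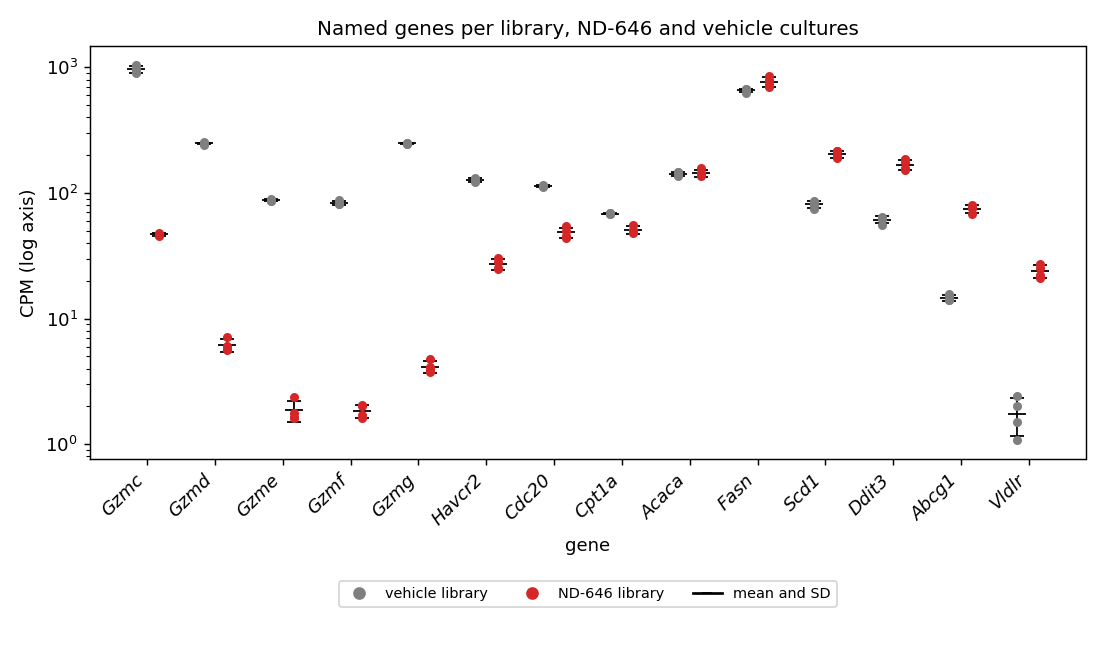
CPM on a log axis of 14 genes in each of 4 vehicle and 4 ND-646 libraries (points), with the mean and SD as bars. Gzmc fell from a mean of 970 to 46.9 CPM, whereas Acaca stood at 142 and 144 CPM.

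The transcripts of the inhibited enzymes passed no test. Acaca, the cytosolic carboxylase, was at 142 ± 5.72 CPM in vehicle and 144 ± 9.17 CPM in ND-646 libraries (SD, n = 4 each), with a log2 fold change of 0.02 ± 0.05 (SE) and an adjusted p of 0.797. Acacb, the mitochondrial form, was scarce at 2.64 ± 0.129 and 3.06 ± 0.269 CPM (adjusted p = 0.177). Fasn, fatty acid synthase, rose by 0.22 ± 0.05 on the log2 scale (SE; adjusted p = 0.00148). Cpt1a, which loads fatty acids for mitochondrial import, fell by 0.43 ± 0.05 (adjusted p = 3.92e-07). In the fatty acid synthesis list, 10 of 24 genes rose and 8 fell, with camera adjusted p = 0.0318 and adjusted p = 0.242 with an estimated correlation. Its 2 smallest p-values were those of the stearoyl-CoA desaturases, with log2 fold changes of 1.33 ± 0.05 for Scd1 and 0.78 ± 0.04 for Scd2 (SE). Fatty acid oxidation genes moved both ways, 9 higher and 9 lower of 28 (camera adjusted p = 0.866), with Acaa1a, a peroxisomal thiolase, 0.45 ± 0.04 higher.

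Cholesterol synthesis and uptake genes fell in 22 of 25 cases and rose in none, with a median log2 fold change of -0.33. Mvk, mevalonate kinase, changed by -0.60 ± 0.05 and Fdps, farnesyl diphosphate synthase, by -0.53 ± 0.04 (SE). The list passed camera (adjusted p = 2.58e-06) but not with an estimated correlation (adjusted p = 0.263). Of 26 genes of lipid uptake, storage and lipolysis, 11 rose and 7 fell (adjusted p = 0.0144, and adjusted p = 0.242 with an estimated correlation). The sterol exporter Abcg1 rose by 2.36 ± 0.06, Acsl3, an acyl-CoA synthetase, by 1.26 ± 0.05 and Vldlr by 3.79 ± 0.17 (SE).

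Effector genes fell in 17 of 26 cases and rose in 5, a call that held with an estimated correlation (adjusted p = 9.02e-05). Gzmd, Gzme, Gzmf and Gzmg had log2 fold changes of -5.33, -5.54, -5.50 and -5.90, with standard errors of 0.0564 to 0.0753. These paralogs share sequence, so the division of reads among them is uncertain. Outside that cluster, Gzma, another granzyme, changed by -2.13 ± 0.05 and Prf1, the pore-forming perforin, by -2.56 ± 0.14 (SE). Gzmb, the most abundant granzyme named here and a neighbour of the Gzmc group in that cluster, changed by -0.86 ± 0.05, from 3652 to 2018 CPM. Tnf, at 77.7 CPM in both groups, had an adjusted p of 0.984.

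Exhaustion and inhibitory receptor genes fell in 12 of 25 cases and rose in 7, and the list passed under both correlations (adjusted p = 0.00585 when estimated). In the same libraries as these and the other lists, macrophage, monocyte and neutrophil markers fell in 8 of 9 cases and NK and gamma delta T cell markers in 6 of 8. Cd244a and Havcr2, which encode the inhibitory receptors 2B4 and TIM-3 and are also expressed by NK and myeloid cells, changed by -2.40 ± 0.05 and -2.22 ± 0.06 (SE). Lag3 and Pdcd1 also fell, by 1.70 and 1.17 on the log2 scale, whereas Tox rose by 0.56. Among 17 tissue residency genes, 9 fell and 4 rose (adjusted p = 0.00593, and adjusted p = 0.0622 with an estimated correlation), with the chemokine receptor Cxcr6 at -1.92 ± 0.07 (SE). Naive and memory genes went the other way, 14 higher and 6 lower of 25 (adjusted p = 0.0415, and adjusted p = 0.444 with an estimated correlation). That call was lost without vehicle replicate 1 (adjusted p = 0.0562) and without ND-646 replicate 3 (adjusted p = 0.0637). Ccr7, a lymph node homing receptor, rose by 0.62 ± 0.04 and the survival gene Bcl2 by 0.53 ± 0.04 (SE).

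The 36 cell cycle genes had a median log2 fold change of -0.91 (adjusted p = 2.48e-26, and adjusted p = 0.133 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, changed by -1.23 ± 0.05 and thymidine kinase Tk1 by -0.85 ± 0.04 (SE). In the list of endoplasmic reticulum stress and amino acid response, 24 of 34 genes rose and 7 fell (adjusted p = 4.82e-07, and adjusted p = 0.33 with an estimated correlation). Cth, which makes cysteine, rose by 2.04 ± 0.11 and the stress transcription factor Ddit3 by 1.45 ± 0.06. Hypoxia response genes rose in 16 of 21 cases and fell in 3 (adjusted p = 0.000159, and adjusted p = 0.0622 with an estimated correlation), among them the oxidase Ero1l at 0.95 ± 0.04 and Nrn1 at 1.56 ± 0.07. Type I interferon response genes rose in 19 of 27 cases and fell in 2 (adjusted p = 0.00442, and adjusted p = 0.444 with an estimated correlation), with the RNA sensors Ddx58 and Ifih1 at 0.56 ± 0.04 and 0.78 ± 0.06.

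Glycolysis genes moved both ways, 9 higher and 6 lower of 22 (adjusted p = 0.524). Pdk1, a kinase that restrains pyruvate dehydrogenase, rose by 0.37 ± 0.04, while the phosphofructokinase Pfkp fell by 0.42 ± 0.04 on the log2 scale. Nuclear genes of oxidative phosphorylation fell in 28 of 41 cases and rose in 1 (adjusted p = 0.00166, and adjusted p = 0.444 with an estimated correlation), with Cox5b and Cox5a, subunits of cytochrome c oxidase, at -0.54 ± 0.04 and -0.44 ± 0.04. Mitochondrially encoded mRNAs fell in 11 of 13 cases (median -0.94; adjusted p = 3.32e-12, and adjusted p = 0.0601 with an estimated correlation). Their share of counts was 2.88% ± 0.168 in vehicle and 2.13% ± 0.0178 in ND-646 libraries (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). Within the list mt-Cytb, cytochrome b, changed by -1.58 ± 0.09 and mt-Co2 by -0.85 ± 0.07, but mt-Co1, the most abundant, by -0.13 ± 0.04.

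Markers of other cell types also moved. Macrophage, monocyte and neutrophil markers fell in 8 of 9 tested cases, a call that held with an estimated correlation (adjusted p = 0.0081). That list holds 24 genes, and the rest had too few counts to be tested. Spp1, osteopontin, stood at 229 ± 5.96 and 54.1 ± 6.14 CPM, and Ccr2, a chemokine receptor that T cells can also express, at 66.5 ± 10 and 12.3 ± 0.81 CPM (SD, n = 4 each). Which cells made these transcripts was not measured. NK and gamma delta T cell markers fell in 6 of 8 cases and rose in 1 (adjusted p = 0.00174, and adjusted p = 0.0601 with an estimated correlation). There the adaptor Fcer1g went from 14.4 to 2.86 CPM, Sox13 changed by -0.59 ± 0.07, and Trdc rose by 0.24 ± 0.04. CD4 and regulatory T cell markers fell in 8 of 9 cases and rose in 1 (adjusted p = 0.0144, and adjusted p = 0.263 with an estimated correlation), including Il2ra, the interleukin-2 receptor alpha chain that activated CD8+ cells also carry, at -0.79 ± 0.04, while Zbtb7b rose by 0.35 ± 0.04. B cell markers fell in 7 of 10 cases and rose in 1 (adjusted p = 0.0607, and adjusted p = 0.264 with an estimated correlation), and passed at the preset correlation in 7 of the 8 fits without 1 library (adjusted p = 0.0246 to 0.0471), all but that without vehicle replicate 4. The low-count filter left 10 to 12 members tested in those fits, so they do not all cover the same genes. The member that rose was Ighm, at 0.50 ± 0.05, and immunoglobulin genes took 0.0146% ± 0.000673 of vehicle and 0.0193% ± 0.00116 of ND-646 counts (SD, n = 4 each; exact permutation p = 0.0286).

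CD8 identity genes moved both ways, 7 higher and 7 lower of 17 (adjusted p = 0.753), with Thy1 at -0.46 ± 0.04. Dendritic cell markers (2 higher, 4 lower of 10; adjusted p = 0.174), fibroblast markers (1 higher, 4 lower of 8; adjusted p = 0.342) and endothelial markers (4 lower of 4; adjusted p = 0.073) did not pass. Their most abundant members were Batf3 at 58.5 and 58.9 CPM, Col6a2 at 4.87 and 6.68 CPM and Pecam1 at 37.5 and 26.7 CPM. The 1 tested erythroid or platelet gene, Itga2b, stood at 8.89 and 8.67 CPM (adjusted p = 0.712). The other genes at the top of the ranking were Cox6a2, a muscle-type oxidase subunit, Aldh1l2, a mitochondrial folate enzyme, Phyhd1 and the transglutaminase Tgm2, with log2 fold changes of 3.60, 2.80, 2.60 and 2.52.

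**Figure D2:**
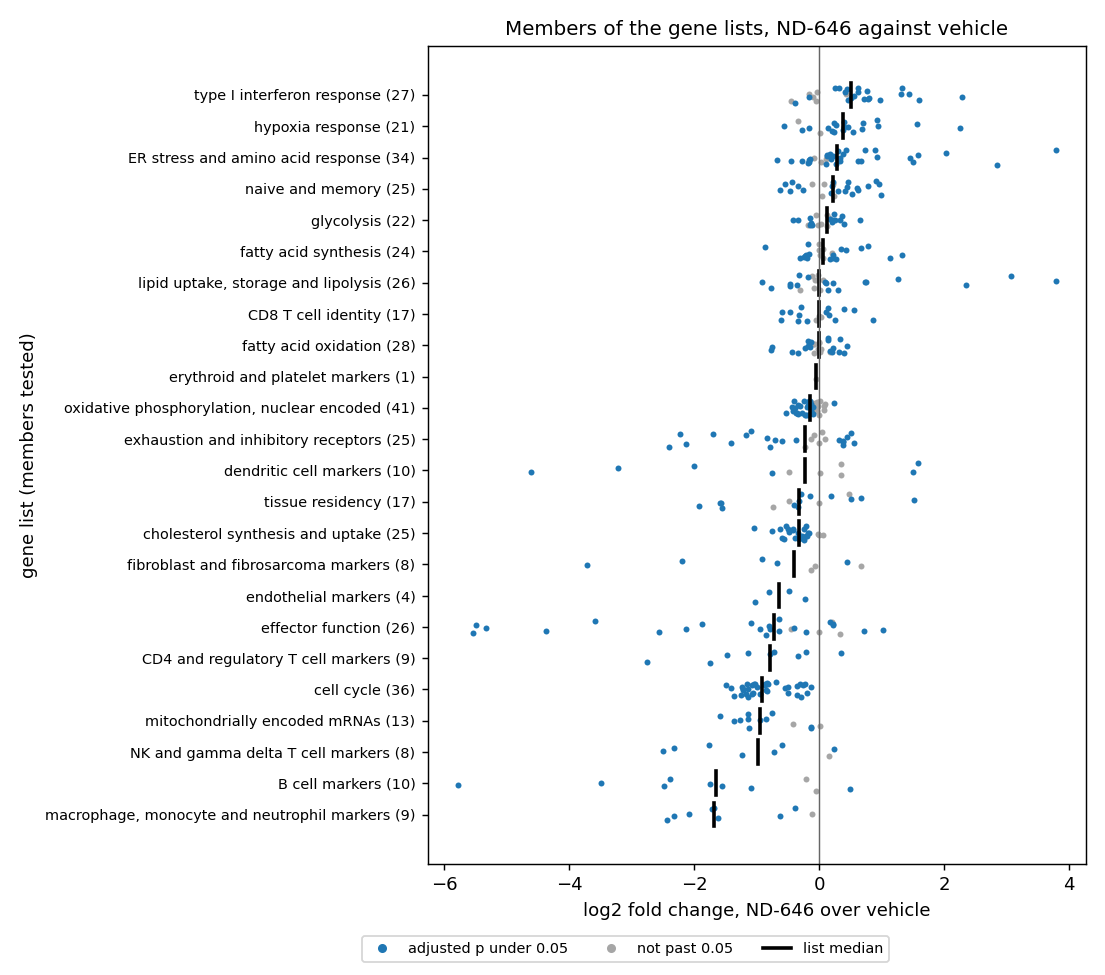
Log2 fold change of ND-646 over vehicle (horizontal axis) for each tested member (points) of the 24 gene lists (rows, with members tested), coloured by whether the adjusted p was under 0.05. Black bars are list medians, which run from -1.68 for macrophage, monocyte and neutrophil markers to 0.51 for the type I interferon response. The median of B cell markers was -1.65, and between -2.27 and -1.67 with 1 library left out, where 10 to 12 members were tested.

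Of the 23 lists tested, 16 passed with the preset correlation and 3 with an estimated one. Counts adjusted over the list alone were the same except for oxidative phosphorylation (2 higher, 28 lower), mitochondrial mRNAs (12 lower), effector function (5 and 18), naive and memory (16 and 7) and tissue residency (4 and 10). With a minimum change of 2-fold, 998 genes passed, 375 higher and 623 lower.

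The second comparison asked how CD8+ T cells from tumours differed from those of spleen. Tumour libraries held abundant RNA of connective tissue beside T cell RNA. Col3a1, a fibrillar collagen, stood at 1.47 ± 2.16 CPM in spleen and 3083 ± 488 CPM in tumour libraries, and fibronectin Fn1 at 1.23 ± 1.57 and 2355 ± 370 CPM (SD, n = 3 each). Most of their spleen counts came from spleen replicate 1, without which their log2 fold changes went from 11.01 and 10.88 to 13.73 and 12.83. All 26 tested fibroblast and fibrosarcoma markers were higher. On the lists of T cell state, whose genes other cells can also express, the activation-induced receptors Nr4a2 and Nr4a3 rose by 6.73 ± 0.11 and 4.83 ± 0.07 on the log2 scale (SE), interferon gamma (Ifng) by 5.83 ± 0.18, and Tcf7, a transcription factor of naive and memory cells, changed by -3.36 ± 0.07. Of 15042 genes tested, 12602 passed, 6551 higher (52.0%) and 6051 lower. Scaled by CD8 identity genes instead, 12290 passed, 10501 higher (85.4%) and 1789 lower, and the median of all genes shifted by 0.984 on the log2 scale.

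CD8 identity genes fell in all 17 cases (median -0.96; adjusted p = 0.00132, and adjusted p = 0.49 with an estimated correlation). Cd8a changed by -0.69 ± 0.11 and Thy1 by -0.33 ± 0.09 (SE), which turned to 0.28 and 0.64 when scaled by the identity genes. That scaling holds the mean of this list near 0 by construction, so its members scatter around 0. It takes these genes as constant per T cell, which was not tested. The fibroblast list had a median log2 fold change of 11, also with genes at 0 in spleen held at their bound, and adjusted p = 2.2e-17, or adjusted p = 0.264 with an estimated correlation. The median was 13.5 without spleen replicate 1 and 10.4 without spleen replicate 3. The 5 highest genes had no count in spleen. Against 3 counts over the spleen group, Cpe, a peptide-processing enzyme, was at least 3940-fold higher, the transcription factor Sox9 at least 1750-fold, the collagen Col8a1 at least 1640-fold, Bmp2, a secreted growth factor, at least 1230-fold and the complement protease C1s1 at least 1090-fold. The 5 lowest were Kcna2, Slc16a5, Jchain, Xkrx and Lrrc75b, with log2 fold changes of -7.33, -7.23, -6.46 (-7.452 without tumour replicate 3), -6.43 and -6.37.

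Other cell markers also moved. NK and gamma delta T cell markers rose in 10 of 11 cases and fell in 1 (adjusted p = 0.107), with Klre1 at 2.86 and 23.5 CPM. Macrophage, monocyte and neutrophil markers rose in 10 of 15 cases and fell in 1 (adjusted p = 0.236), with Spp1 at 0.226 ± 0.348 and 385 ± 64.4 CPM (SD, n = 3 each), where the log2 fold change of 10.67 became 13.62 without spleen replicate 1. Dendritic cell markers (6 higher, 1 lower of 12; adjusted p = 0.383) included Fscn1 at 2.08 and 320 CPM, a gene that fibroblasts also express. Endothelial markers rose in 9 of 11 cases and fell in 1 (adjusted p = 0.145), the exception being Pecam1 at -2.62 ± 0.06. B cell markers fell in 8 of 10 cases and rose in 1 (adjusted p = 0.00485, and adjusted p = 0.264 with an estimated correlation), with Ighm at 704 ± 17 and 57.6 ± 7.89 CPM and Igkc at 81.1 ± 2.19 and 1.30 ± 0.991 CPM (SD, n = 3 each). CD4 and regulatory T cell markers rose in 4 of 7 cases (adjusted p = 0.134), with Il2ra 4.98 ± 0.19 higher. Itga2b, the only erythroid or platelet gene tested, changed by -0.66 ± 0.21, or 0.31 when scaled by CD8 identity genes. Its call was lost without spleen replicate 3 (adjusted p = 0.0572) and without tumour replicate 3 (adjusted p = 0.0568).

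Exhaustion and inhibitory receptor genes rose in 23 of 27 cases and fell in 2, with a median log2 fold change of 3.27 (adjusted p = 1.98e-09, and adjusted p = 0.253 with an estimated correlation). Tissue residency genes rose in 13 of 17 cases and fell in 1 (adjusted p = 3.09e-07, and adjusted p = 0.209 with an estimated correlation), with Litaf at 6.01 ± 0.10 and Rgs2 at 4.48 ± 0.10 (SE). Effector genes rose in 24 of 28 cases and fell in none (adjusted p = 9.6e-05, and adjusted p = 0.395 with an estimated correlation), among them Il12rb2, an interleukin-12 receptor chain, at 5.49 ± 0.19. Naive and memory genes fell in 21 of 25 cases and rose in 3 (adjusted p = 3.21e-09, and adjusted p = 0.253 with an estimated correlation), including Il6ra at -3.37 ± 0.07. Beside each of these lists the connective tissue markers were higher by the amounts given above.

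All 36 cell cycle genes rose (median 3.12; adjusted p = 2.64e-15, and adjusted p = 0.264 with an estimated correlation), with Ccnb1, a mitotic cyclin, at 4.11 ± 0.08 and Tk1 at 3.01 ± 0.06. Glycolysis genes rose in 21 of 22 cases and fell in 1 (adjusted p = 4.94e-07, and adjusted p = 0.24 with an estimated correlation), with Tpi1 at 3.18 ± 0.07 and the lactate transporter Slc16a3 at 5.30 ± 0.12 (SE). Hypoxia response genes rose in 17 of 22 cases and fell in 4 (adjusted p = 0.000235, and adjusted p = 0.321 with an estimated correlation), including Mxi1 at 2.28 ± 0.08 and Slc6a8 at 7.19 ± 0.24. Of the endoplasmic reticulum stress and amino acid list, 31 of 34 rose and 2 fell (adjusted p = 2.11e-07, and adjusted p = 0.264 with an estimated correlation), with Xbp1 at 2.04 ± 0.05 and Cebpb at 3.76 ± 0.10. Type I interferon response genes fell in 21 of 31 cases and rose in 7 (adjusted p = 0.00517, and adjusted p = 0.465 with an estimated correlation). When scaled by CD8 identity genes that list split into 13 higher and 4 lower. Ddx58 changed by -1.32 ± 0.06, or -0.32 with that scaling (adjusted p = 0.0561), and Oas2 by -2.68 ± 0.12.

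Cholesterol synthesis and uptake genes rose in 22 of 24 cases and fell in none (median 1.81; adjusted p = 2.3e-10, and adjusted p = 0.209 with an estimated correlation), with Cyp51, a sterol demethylase, at 3.02 ± 0.05 and Insig1 at 2.61 ± 0.06. Fatty acid synthesis genes rose in 17 of 23 cases and fell in 5 (adjusted p = 0.0346, and adjusted p = 0.253 with an estimated correlation), with Scd2 at 2.60 ± 0.07 and the acetyl-CoA synthetase Acss2 at -2.33 ± 0.08. Acaca rose by 0.48 ± 0.04 and Fasn by 0.65 ± 0.05, while Acacb changed by -1.39 ± 0.31 (SE; adjusted p = 0.002), a call lost when scaled by CD8 identity genes (-0.43; adjusted p = 0.234). Cpt1a changed by -0.40 ± 0.10, or 0.58 when scaled by CD8 identity genes. Fatty acid oxidation genes split into 13 higher and 8 lower of 28 (adjusted p = 0.971), with a median of 0.19 although camera's direction was lower. Scaled by CD8 identity genes, the median was 1.18 and camera's direction was higher (adjusted p = 0.654). Acadl, an acyl-CoA dehydrogenase, rose by 0.91 ± 0.06 and Cpt1c by 5.99 ± 0.39 (6.704 without spleen replicate 1). Lipid uptake, storage and lipolysis genes (18 higher, 6 lower of 28; adjusted p = 0.232) included Dgat1, which makes triglyceride, at 3.76 ± 0.12 and Acsl4 at 1.19 ± 0.05.

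Nuclear oxidative phosphorylation genes rose in 32 of 41 cases and fell in 4 (adjusted p = 0.103, but 0.048 without tumour replicate 3 and 0.00738 when scaled by CD8 identity genes), with Cox5a at 1.00 ± 0.05 and Cycs at 0.99 ± 0.05. Mitochondrially encoded mRNAs fell in 11 of 13 cases (adjusted p = 0.0622, and 0.035 without spleen replicate 1), but 12 were higher when scaled by CD8 identity genes, and mt-Co1 changed by -0.42 ± 0.05, or 0.57 with that scaling. Ribosomal protein genes took 11.3% ± 0.147 of spleen and 6.68% ± 0.298 of tumour counts (SD, n = 3 each; exact permutation p = 0.1, the smallest possible).

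**Figure D3:**
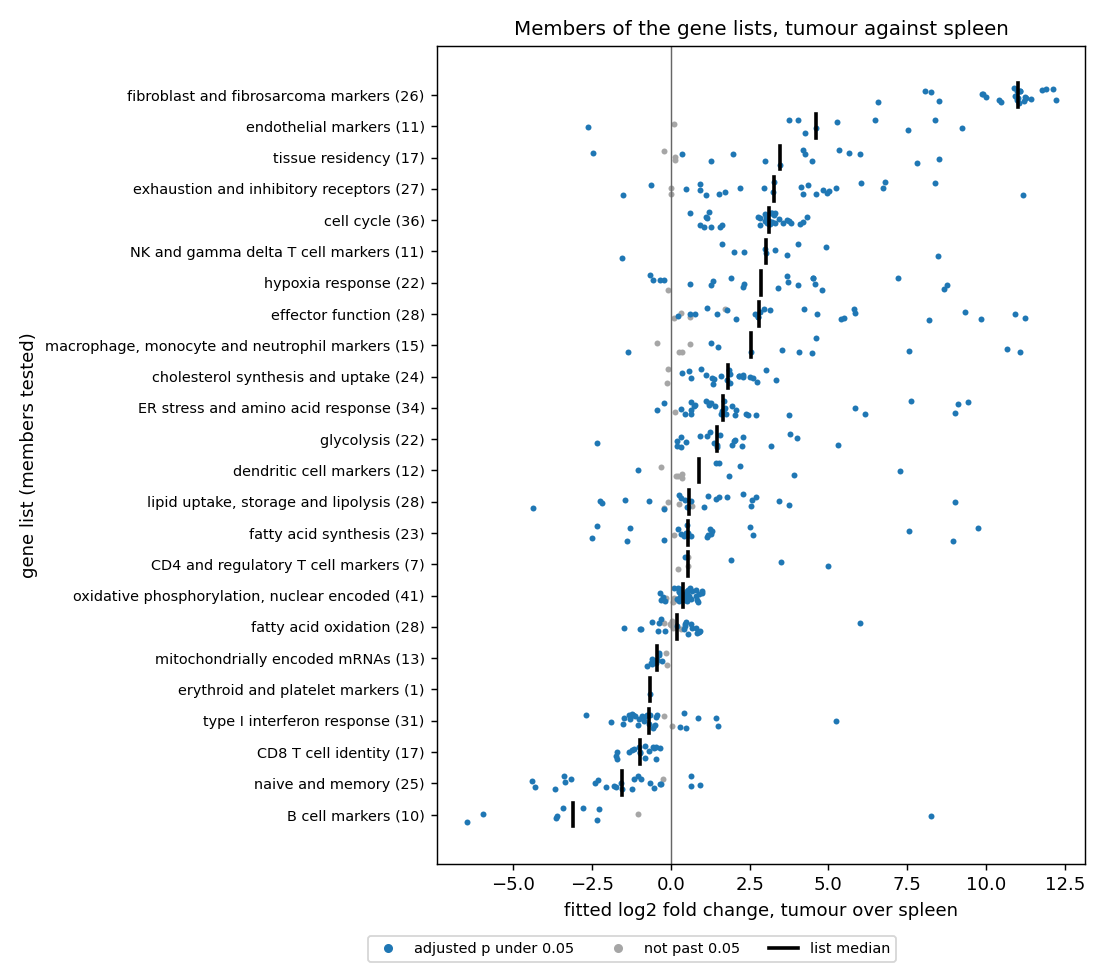
Fitted log2 fold change of tumour over spleen (horizontal axis) for each tested member (points) of the 24 gene lists (rows, with members tested), coloured by whether the adjusted p was under 0.05. Black bars are list medians, from -3.10 for B cell markers to 11 for fibroblast and fibrosarcoma markers (13.5 without spleen replicate 1). Under scaling by CD8 identity genes the medians of CD8 identity, mitochondrial and interferon genes were 0.01, 0.56 and 0.30, the first being near 0 by construction.

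With the preset correlation 14 of 23 lists passed, and 0 passed with an estimated one, where 4 had an unadjusted p under 0.05. Counts adjusted over the list alone were the same except for oxidative phosphorylation (34 higher, 5 lower) and B cell markers (1 and 9). At a minimum change of 2-fold, 7026 genes passed, 4134 higher and 2892 lower.

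The 2 comparisons use separate libraries and tables. Of 13261 genes tested in both, 6538 were called in both, and 40.1% of these moved in the same direction (odds ratio 0.436, 95% interval 0.394 to 0.483, Fisher's exact test across genes, which are not independent replicates). In both comparisons 1521 genes were higher, where independent calls would give 1655.8, and 1100 were lower, where they would give 1496.3. Across all 13261 genes the log2 fold changes were only weakly correlated (Pearson -0.131, Spearman -0.136). Scaling the tumour comparison by CD8 identity genes gave 48.3% in the same direction and an odds ratio of 0.558. Gzmg, Gzme and Gzmf were lower under ND-646 and higher in tumour, where Gzmf had 5 counts in spleen and 10516 in tumour, Gzme was at least 305-fold and Gzmg at least 48.5-fold higher. Their log2 fold changes in tumour had standard errors of 1.51 (Gzmf), 0.783 (Gzme) and 1.59 (Gzmg). The bounds cover counting error only, and the division of reads among these paralogs is uncertain. Abca1, Abcg1 and Klhl3 were higher under ND-646 (3.08, 2.36 and 2.28) and lower in tumour (-2.25, -2.19 and -2.07). Klhl3 was scarce, with 26 counts in vehicle and 156 in ND-646 libraries. Vldlr, Pla2g4a and Gfra1 were higher in both, with Pla2g4a at 3.14 and 6.20, and Vldlr and Gfra1 at least 64.5-fold and 52.8-fold higher in tumour. Pla2g4a had only 9 counts in vehicle and 101 in ND-646 libraries (SE 0.469). Itgad and Adgrb2 were lower in both (-2.40 each under ND-646, -2.87 and -3.81 in tumour), as was Igkc, with 69 counts in vehicle and 1 in ND-646 libraries (ratio 0.0118, 95% interval 0.000295 to 0.0681). Itgad had 66 counts in vehicle and 15 in ND-646 libraries, and Adgrb2 84 and 19.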

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

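The splits of the libraries and the test of nuclear copies were set before their results were seen; the tests of the granzymes, of the tumour lists and of the mitochondrial genes with a copy were chosen afterwards. Of 116 groups of 4 libraries examined in the first experiment, 2 had a library far from the others, where chance gives about 5.8. One vehicle library (replicate 3) had 15990 CPM of mt-Co1, against 14470 to 14680 in the others. One ND-646 library (replicate 1) had 563.7 CPM of Il2ra, against 589.4 to 591.5.

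Other splits of the libraries were tried for both counts of called genes. Of the 35 splits of the 8 culture libraries, 1 gave as many calls as the real 8028, the real split itself. The highest of the others gave 1. All the others mixed vehicle and ND-646 libraries, so a group difference would itself raise their spread and lower their calls. The calls thus followed the labels of the libraries. Replicates may be technical, so a chance difference between cultures cannot be excluded by this test. The 6 spleen and tumour libraries allow 10 splits, too few for a share under 0.05. The real split, 1 of them, gave 12602 calls and the highest other 0.

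The first pattern is the fall of Gzmc, Gzmd, Gzme, Gzmf, Gzmg and Gzmn under ND-646. Reads moved between these paralogs would leave their sum in place, but the summed CPM fell from 1638 to 60.9, a log2 fold change of -4.75 ± 0.04 (SE), and with their neighbour Gzmb, which that sum leaves out, from 5290 to 2078 (-1.35 ± 0.0457). Receptors and adaptors of NK cells fell as well, from 29.9 to 9.24 summed CPM, a loss of 0.0224 of that of Gzmc. How much Gzmc goes with them in an NK cell was not measured, so fewer NK cells and a change within T cells cannot be told apart. An effect of the inhibitor on T cells also stays open, and an indirect effect of the lower cell cycle genes was not tested.

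The second pattern is the mixture of RNA in tumour libraries, in which fibroblast genes and CD8 identity genes moved apart between libraries of 1 group (log2 differences of 0.527 and -0.406 between tumour libraries 1 and 2). On a scale from 0 for CD8 identity to 1 for fibroblast genes, hypoxia genes lay at 0.868 (95% bootstrap interval 0.433 to 1.14), exhaustion genes at 0.0285 (-0.101 to 0.281) and glycolysis genes at 0.492 (0.326 to 0.66). Between libraries 1 and 3 they lay at 0.93 (0.431 to 0.998), 0.319 (0.106 to 0.553) and 0.463 (0.343 to 0.62), and between 3 and 2 at 0.753 (0.451 to 1.28), 0.0317 (-0.983 to 0.475) and 0.451 (0.0762 to 0.676). The bootstrap resampled the genes of each list and of the 2 reference lists within 1 pair of libraries. Its intervals thus hold no spread between libraries, and the 3 pairs are drawn from the same libraries. An interval on 1 side of 0.5 in both of the first 2 pairs was needed to decide, and none of the 3 lists met it (the interval of exhaustion genes lay under 0.5 in 2 of the 3 pairs), so RNA of fibrosarcoma or stromal cells and a change within T cells cannot be told apart for them. The few libraries keep this open, and whether such RNA came with cells that passed the sort or as free RNA was not measured. For tissue residency genes, placed in the same way, both intervals lay under 0.5 (0.075 to 0.475 and 0.00317 to 0.459). So did those of naive and memory genes (0.138 to 0.445 and -0.46 to 0.138) and oxidative phosphorylation genes (0.3 to 0.416 and 0.0608 to 0.365). These lists thus met the rule, whose first 2 pairs share library 1. Between libraries 3 and 2, however, naive and memory genes lay over 0.5 (0.739 to 1.46) and the others spanned it. That pair was not part of the rule, but it did not bear out the first 2, so these lists are left undecided.

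The third pattern is the uneven fall of mitochondrial mRNAs under ND-646, from -1.58 for mt-Cytb to 0.01 for mt-Nd6. With the counts of nuclear copies added the spread was 1.59 ± 0.125 (SE), but the 2 genes at its ends have no annotated copy, so adding copies could not move it and this test decides nothing. Among the 9 genes with an annotated copy the spread was 1.31 ± 0.101 with copies added, but the copies of mt-Nd5 and mt-Nd2 held no counts, which kept it at 1.01 or more, so this decides nothing either. Copies held most reads of mt-Atp6 (Gm10925, 2481 CPM against 487.9 in vehicle) and of mt-Co3 (Gm28437, 1638 against 488.1), so the values of these 2 genes are uncertain. The 4 genes without an annotated copy were themselves uneven, at -1.58 for mt-Cytb, -1.13 for mt-Nd1, -0.94 for mt-Atp8 and 0.01 for mt-Nd6. Unevenness was thus also present where the search found no copy. These 4 were set apart by that search, so their values cannot test reads shared with copies. The search would have missed a copy below its limits of identity and length, or outside the annotation it used. The annotation behind the counts is not given. Reads shared with nuclear copies stay open for the genes with a copy found and for those without. Copies not annotated, poly(A) selection and an effect of ND-646 on mitochondrial transcripts were not tested and stay open as well.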

How the results depend on the processing

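The CD8 identity scaling and the restriction to genes detected in T cell libraries were chosen after the data were seen; the other alternatives were planned. Called genes numbered 7424 to 8538 in the first comparison and 10743 to 14249 in the second under every alternative except the 2-fold threshold, which left 998 and 7026, since it drops small changes. Lists passing fell from 16 to 3 and from 14 to 0 with an estimated correlation, and ranged over 16 to 17 and 14 to 15 when a library was left out. Naive and memory genes under ND-646 no longer passed without vehicle replicate 1 (adjusted p = 0.0562) or ND-646 replicate 3 (0.0637), while B cell markers passed in 7 of 8 such fits (0.0246 to 0.0471), in which 10 to 12 members were tested. In tumour, mitochondrial mRNAs passed without spleen replicate 1 (0.035), oxidative phosphorylation without tumour replicate 3 (0.048) and with CD8 scaling (0.00738), and Itga2b no longer passed without spleen or tumour replicate 3 (0.0572 and 0.0568). Replicate numbers did not pair the libraries (correlations of deviations -0.121 to 0.0659 and -0.0463 to -0.0193), and the replicate block gave 7864 and 12492 calls. Changes of sign were limited to values near 0 or to the CD8 scaling. Acaca under ND-646 was -0.0001482 with RLE, -0.003528 with the stricter filter and -0.03249 to 0.03343 with a library left out. Batf3 was -0.004334, -0.007584 and -0.05703 to 0.05919. Itga2b ranged from -0.1023 to 0.02941. The fatty acid oxidation medians ranged from -0.0303 to 0.0019 and, in tumour, from 0.169 to 0.293, where camera's direction changed. The tumour minus spleen difference in total counts ranged from -0.2282 to 0.4953 M. CD8 scaling turned Cpt1a to 0.5757, mt-Co1 to 0.5737, Cd8a to 0.2825, Thy1 to 0.6396, Itga2b to 0.3058 and the direction of the oxidation list (median 1.18), because it shifts the median log2 fold change by 0.984; 1987 of the genes called both ways had opposite signs. The causes of the other changes were not tested. The pseudocount alternative was for normalized units and was not run. In simulations at this depth, 48% and 28% of genes at the smallest simulated fold were recovered, so small changes can be missed. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter, so these shares need not hold for the data. A shift in RNA composition was not simulated.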

Other observations

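The test of the liver X receptor hypothesis was chosen after the values were seen, as were the genes named here. Beyond the genes of the report, ND-646 cultures had less S100a4, a calcium-binding protein (202 ± 8.14 and 13.6 ± 0.975 CPM in vehicle and ND-646, SD, n = 4 each), S100a6 (319 ± 8.43 and 77.2 ± 2.67), the receptor Kit (39.1 ± 2.58 and 7.26 ± 2.01) and Cd7 (20.3 ± 0.919 and 2.60 ± 0.804). They had more Stc2, a secreted glycoprotein (23.6 ± 0.642 and 126 ± 5.53 CPM), Nupr1, a stress-induced regulator (15.9 ± 1.05 and 52.8 ± 3.74), the arginine transporter Slc7a3 (10.7 ± 0.438 and 36.2 ± 5.85) and the interferon-induced GTPases Gbp11 (11.6 ± 1.64 and 64.9 ± 11.8) and Iigp1 (6.13 ± 1.28 and 25.9 ± 4.33).

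Of 11 tested genes known as targets of the liver X receptor, a sterol-sensing nuclear receptor, 8 were higher, 2 lower and 1 did not pass, with log2 fold changes of 3.08 for Abca1, 2.36 for Abcg1, 2.16 for Mylip, 1.33 for Scd1 and 0.68 for Srebf1, while Pltp and Apoe changed by -0.56 and -0.38. A candidate explanation is sterol excess, which would also lower cholesterol synthesis genes. These had a median log2 fold change of -0.328 with 22 of 25 lower, which is consistent with it, but fewer dividing cells would be too, and sterols were not measured. In tumour libraries Abca1 and Abcg1 were lower and the synthesis genes higher, but Scd2, another of the 11 targets, was 2.60 higher on the log2 scale. Those libraries also held abundant connective tissue RNA, so a change within T cells cannot be read from this.

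Of the 4134 genes at least 2-fold higher in tumour, 1325 (32.1%) were under 1 CPM in every spleen and culture library. Genes under 1 CPM in all those libraries took 2.61%, 3.63% and 3.3% of counts in the tumour libraries. If the tumour libraries held only 2 sources of RNA, the share not from T cells would be 35.8% in library 1 from libraries 1 and 2, but 27.8% from libraries 1 and 3. For library 3 the estimates were 36% and 56.6%, so no single share is given.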
